A study of Mus musculus with 6 samples.

How the data were processed

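RNA sequencing was carried out on mouse embryonic stem cells of the TT2 line, derived from a cross of a C57BL/6 female with a CBA male. Per the labels, 3 libraries came from wild-type cells and 3 from cells lacking both alleles of G9a, the histone H3K9 methyltransferase encoded by Ehmt2. The cells were grown in medium with serum and the cytokine LIF, total RNA was purified with a Qiagen kit, and poly-A libraries were made with an Illumina kit. The labels number the libraries 1 to 3 in each genotype. They do not say whether these came from separate cultures, or how many knockout clones were used, so the p-values measure only the spread between these libraries, which can be technical.

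The deposited table lists read counts for 55419 UCSC transcript identifiers in the 6 libraries. Per the submitters' processing notes, the genome build was mm9 and the tools included Bowtie 0.12.7, R 2.12.1 and DESeq2. The notes do not give each tool a role. The read counter, the strand setting and the treatment of reads that align to several places are not given in the sources used here. Reads from overlapping transcripts, antisense partners or near-identical copies can therefore be split or shared between identifiers in an unknown way.

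A further set of deposited columns holds normalized counts, treated here as a score with no fixed unit because the authors rounded them to whole numbers. All of these values lay within 0.51 of the raw count divided by the DESeq2 median-of-ratios size factor of its library. The authors' deposited log2 fold changes compare knockout with wild type. The authors' deposited p-values come with a Benjamini-Hochberg adjusted column, and 8667 identifiers have a p-value and no adjusted one. These columns were used to set the authors' calls beside the recomputed ones.

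The recomputed test started from the raw counts. Identifiers with too few reads were removed with filterByExpr of edgeR 4.0.16 under R 4.3.3, which kept 12713 of 55419 identifiers, 22.9% of the table. A total of 27309 identifiers had no read in any library. The tested identifiers held 99.6% of the counts of each library. Library sizes were scaled with TMM factors, and genotypes were compared with the edgeR quasi-likelihood test (glmQLFit and glmQLFTest), with no covariate. An adjusted p under 0.05 after Benjamini-Hochberg adjustment is called changed, and the words higher, lower, rose and fell refer to knockout relative to wild type. The standard error of a log2 fold change was taken from the quasi-likelihood F value. Levels are in CPM, counts relative to the TMM-scaled library total, as mean ± SD over the 3 libraries of a genotype.

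The library totals ran from 5738463 to 9717847 counts. Per-transcript intervals and floors cover counting error only, since the reads carry no molecular identifiers. A floor of 3 reads over the 3 libraries of a genotype stands in for a count of 0, and ratios against 1 read carry a 95% exact binomial interval.

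The test, its threshold, the alternatives and the rule for named genes were chosen before the data were examined. The rule asked for the largest changes among transcripts with adjusted p under 0.05, a mean of at least 2 CPM over the 6 libraries and no overlap between the genotypes. Its parts on gene symbols could not be applied, because the table does not pair its identifiers with gene names and no table used here does. For the same reason only 2 identifiers per direction are named, no chromosome positions are given, the transcript level of Ehmt2 itself was not analysed here, and the planned tests of gene lists (chromatin regulators, Polycomb targets, germline, pluripotency, lineage and imprinted genes) were not run. Checks of GC content and transcript length would have been void, since no identifier had a value.

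The identifiers were also examined in the order in which the table lists them, a step chosen after the data were seen. Transcripts at 8 CPM or more were averaged in bins of 10, with log2 fold changes limited to between -1 and 1. Runs of bins with a different mean were then searched for by recursive splitting, each split tested against 199 shuffled orders at p of 0.01 or below. Runs of at least 50 such transcripts with a median at least 0.2 away from that of all such transcripts were kept. Intervals of the shifts came from 1000 bootstrap resamples of bins. They do not allow for the search itself. The identifiers carry no coordinates here, so what the order follows is not stated in the sources used.

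Alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 and upper-quartile scaling factors, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, and stricter thresholds. DESeq2 was run on all identifiers of the deposited table with its own filter on low counts, so that setting changes the filter as well as the test. Leaving out the lower runs and thinning all libraries to the lowest total were added after the data were seen. The edgeR step was tested on simulated counts for 12713 transcripts with this comparison's means and library sizes. It recovered 37 of 67 changes planted at 1.5-fold (55.2%), 53 of 67 at 2-fold (79.1%) and 61 of 66 at 4-fold (92.4%), and 7 of its 158 calls (4.43%) had no planted change. Only 200 changes were planted, against 5080 calls in the data, so the adjusted threshold was harder to pass in the simulation. These recovery shares do not carry over to the data. The search along the table recovered all 300 transcripts of 1 planted run, shifted by about as much as the runs found in the data. It found 0 runs where none was planted. Those simulated counts held no other change along the table and no link between neighbours. They do not test shorter runs, or false runs where neighbouring transcripts change together. The planted run also began and ended at the edges of bins, so its exact recovery does not carry over to runs with other edges.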

Results

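G9a, with its partner GLP, places methyl groups on lysine 9 of histone H3, a modification associated with gene repression. The series asks how these enzymes bear on silencing by Polycomb repressive complex 2, and the RNA measurements compare transcript levels between wild-type and G9a knockout TT2 embryonic stem cells. There were 3 poly-A RNA-seq libraries per genotype. The wild-type libraries held 9717847, 6478010 and 9571001 counts for replicates 1, 2 and 3, and the knockout libraries 8800809, 9172131 and 5738463. Between 21210 and 23186 transcript identifiers had at least 1 read in a library. The 10 most abundant took 8.94% ± 0.54 of the counts in wild type and 8.94% ± 0.29 in knockout (SD, n = 3 each).

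Libraries of one genotype resembled each other more than libraries of different genotypes. The chi-square per degree of freedom between pairs of libraries ran from 1.85 to 6.39 within a genotype and from 16.5 to 29.5 between genotypes. Every pair within a genotype differed by more than counting noise, so none was taken for a library listed more than once. This does not show that the libraries came from separate cultures. Across transcripts, which are not independent replicates, Pearson's r of log2 CPM was 0.985 to 0.992 within and 0.951 to 0.958 between genotypes.

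Loss of G9a went with a broad change in the transcriptome, in which the large changes were almost all increases. Of 12713 transcripts tested, 2744 rose and 2336 fell in knockout cells, 5080 together or 40.0% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per genotype). The other 7633 did not pass the threshold. Most changes were small. The median rise was 0.67 on the log2 scale (1.60-fold) and the median among transcripts that fell was -0.50 (1.42-fold lower in knockout). A rise of at least 1 on the log2 scale was seen for 961 transcripts and a fall of that size for 305. At 2 or more the counts were 391 against 13, and at 3 or more 218 against 1. With 1 library left out and the low-count filter repeated, the 391 became 433 to 498. The 13 became 19, 23 and 20 without wild-type replicate 1, 2 and 3 and 32, 36 and 30 without knockout replicate 1, 2 and 3. That filter is looser with fewer libraries.

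The genotypes did not overlap for 49.2% of the tested transcripts, where chance gives 10%. In 3269 all knockout libraries lay above all wild-type libraries and in 2990 all lay below. Among the transcripts called, 2656 of the 2744 that rose and 2215 of the 2336 that fell showed this separation. The biological coefficient of variation was 5.16%. The share of higher calls, 54.0% of all changed transcripts, depended on the scaling, as upper-quartile factors gave 2411 higher and 2774 lower (46.5% higher). With DESeq2 and its own low-count filter in place of edgeR and filterByExpr, the number of lower transcripts was 1440. With edgeR and no low-count filter the numbers past 2 on the log2 scale were 810 higher and 98 lower.

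**Figure D1:**
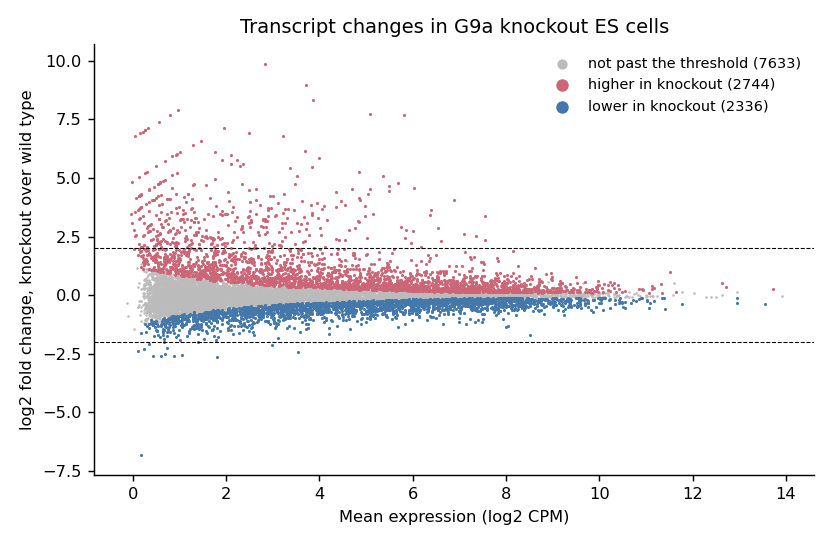
Log2 fold change of knockout over wild type (vertical axis) against mean expression in log2 CPM (horizontal axis) for the 12713 transcripts tested, 1 point per transcript, with 2744 higher in red, 2336 lower in blue and 7633 not past the threshold in grey. Beyond the dashed lines at 2 and -2 lie 391 higher and 13 lower transcripts among those called.

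Most of the transcripts that rose most were weakly expressed in wild-type cells, although 76 of the 391 had a mean of at least 2 CPM in both genotypes. The 391 that rose by at least 2 on the log2 scale had a median of 0.565 CPM in wild type (interquartile range 0.241 to 1.43) and 4.89 CPM in knockout (2.62 to 14.0). The median of all tested transcripts was 8.01 CPM in wild type and 8.69 CPM in knockout. The per-library medians of the 391 transcripts were 0.468 to 0.610 CPM in the wild-type libraries and 4.65 to 4.86 CPM in the knockout libraries. The 305 transcripts that fell by at least 1 on the log2 scale went from a median of 3.45 CPM in wild type to 1.41 CPM in knockout. These groups were selected for their change, so the medians describe them and do not test it.

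Some transcripts were detected almost only in the knockout. In the table, 52 transcripts had at most 3 reads over the 3 wild-type libraries and at least 10 reads in each knockout library, of which 51 were called higher. Only 1 transcript showed the reverse. With 0 reads in all wild-type libraries the number was 5, against 1 in the reverse direction.

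By level of expression, the strong increases were most frequent among weakly expressed transcripts. In the lowest quartile group of mean expression (0.913 to 2.77 CPM) 192 transcripts rose and 10 fell by 2 or more on the log2 scale, and in the highest group (50.9 to 15381 CPM) 18 rose and 0 fell. Calls of any size numbered 442 higher and 214 lower in the lowest group, and 933 higher and 960 lower in the highest.

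The largest increases by fitted fold change under the naming rule belonged to identifiers only 3 rows apart in the table. uc009urm.1 had 0 reads in the wild-type libraries and 336 in the knockout libraries, with a knockout level of 14.2 ± 1.98 CPM (SD, n = 3). It was at least 123-fold higher in knockout, taking the floor of 3 reads over the wild-type group (edgeR adjusted p = 1.26e-11). uc009urj.1 had 1 wild-type read, in replicate 1, and 624 knockout reads, with a knockout level of 26.8 ± 1.62 CPM (SD, n = 3). Its ratio of knockout to wild type was 685 with a 95% counting interval of 123 to 27107 (edgeR adjusted p = 1.12e-14). Whether these identifiers share exons or reads is not given in the sources used here. The authors' deposited table lists log2 fold changes of 5.40 for uc009urm.1 and 6.08 for uc009urj.1.

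The largest decreases under the same rule were smaller. uc009mvt.1 fell from 18.9 ± 0.607 CPM in wild type to 3.44 ± 0.633 CPM in knockout (SD, n = 3 each), a log2 fold change of -2.41 with a standard error of 0.15 (edgeR adjusted p = 9.92e-11). It lies inside one of the lower stretches described next. uc009cis.1 went from 5.40 ± 0.782 CPM in wild type to 0.850 ± 0.841 CPM in knockout (SD, n = 3 each), a log2 fold change of -2.65 with a standard error of 0.42 (edgeR adjusted p = 3.9e-05). Its 20 knockout reads were split as 0, 15 and 5 over replicates 1, 2 and 3. Its log2 fold change was -1.99 without knockout replicate 1 and -3.92 without knockout replicate 2. With DESeq2 in place of edgeR its adjusted p was 0.0665, which misses the threshold of 0.05. The authors' deposited table lists -2.33 for uc009mvt.1 and -1.65 for uc009cis.1.

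The lower transcripts were unevenly spread over the table. In 3 long stretches of consecutive identifiers lay 33.4% of all lower calls and 12.4% of the tested transcripts. Of the 1571 transcripts tested in them, 780 fell (49.6%) and 122 rose (7.77%). Outside the stretches 14.0% fell and 23.3% rose. The median log2 fold change of transcripts at 8 CPM or more was shifted by -0.40 relative to that outside the stretches, with a 95% bootstrap interval of -0.42 to -0.38, a ratio of 0.757 (0.745 to 0.769). Of the 850 such transcripts inside, 85.1% had a log2 fold change below 0, against 45.5% of the 5638 outside.

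The stretches covered rows 13 to 2675, 7665 to 8259 and 40746 to 42966 of the table. In the first, 341 of 702 tested transcripts fell and 70 rose, and the shift was -0.39 (95% interval -0.43 to -0.36). In the next, 94 of 188 fell and 11 rose, with a shift of -0.43 (-0.53 to -0.34). In the last, 345 of 681 fell and 41 rose, with a shift of -0.41 (-0.44 to -0.37). A single stretch went the other way: in rows 36088 to 36681, 50 of 95 tested transcripts rose and 11 fell, with a shift of 0.39 (0.23 to 0.61). Its interquartile range of log2 fold changes was 0.694, against 0.413 outside the stretches.

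Each library carried the shift of its genotype. In the stretch of rows 13 to 2675 the median deviation from the transcript means was 0.19 ± 0.0069 in wild type and -0.20 ± 0.0093 in knockout (log2, SD, n = 3 each). In rows 7665 to 8259 it was 0.22 ± 0.035 and -0.23 ± 0.060, and in rows 40746 to 42966 it was 0.21 ± 0.016 and -0.21 ± 0.0067. In the higher stretch it was -0.19 ± 0.029 in wild type and 0.18 ± 0.015 in knockout. In all 4 stretches the genotypes were fully separated (two-sided exact permutation p = 0.1 each, the smallest that 3 libraries against 3 can give). The stretches were found from the same differences, so this comparison describes how even they are across libraries.

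**Figure D2:**
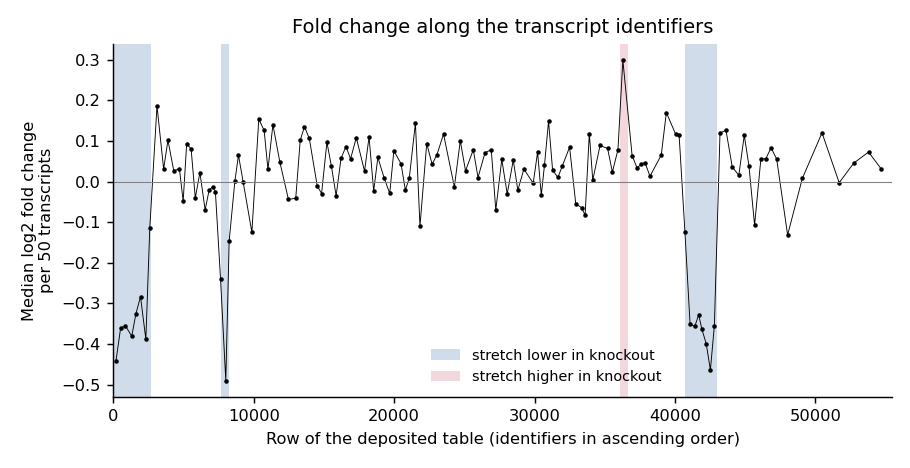
Median log2 fold change of knockout over wild type (vertical axis) in windows of 50 consecutive transcripts at 8 CPM or more, plotted at their row in the table of identifiers (horizontal axis). The 3 stretches lower in knockout (blue bands) have shifts of -0.39, -0.43 and -0.41 relative to the transcripts outside, and the higher stretch (red band) a shift of 0.39.

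**Figure D3:**
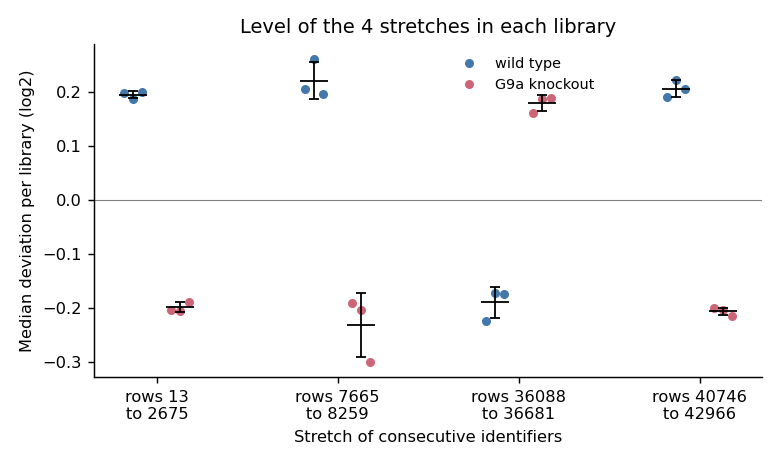
Median log2 deviation of the transcripts at 8 CPM or more in each of the 4 stretches (horizontal axis) from their mean over the 6 libraries, relative to transcripts outside the stretches (vertical axis), with 1 point per library and bars for the mean and SD (n = 3 per genotype). In the 3 lower stretches all wild-type libraries lie above 0 and all knockout libraries below, and in rows 36088 to 36681 the order is the opposite.

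The stretches bear on the counts of all decreases and all increases more than on the strong increases. With the 3 lower stretches left out and the scaling repeated, a setting chosen after seeing the data, 2336 transcripts rose and 1786 fell, and 358 rose and 11 fell by 2 or more on the log2 scale. Of the 2744 increases called with the stretches included, only 122 lay inside them. Calls outside the stretches therefore changed as well in this refit. Inside the 3 lower stretches lay 26 of the 391 strong increases.

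The authors' deposited table has an adjusted p for 19161 identifiers. At the same threshold the authors' deposited table holds 4647 changed transcripts, 2734 higher and 1913 lower. DESeq2 run here called fewer, 3586 changed with 2146 higher and 1440 lower, and the cause of this difference was not tested. Of the calls in the authors' deposited table, 2383 of the higher and 1844 of the lower were also called in that direction by edgeR here. In the opposite direction 0 were called. The authors' deposited table lists 372 higher and 4 lower transcripts past 2 on the log2 scale, where DESeq2 run here gave 535 and 21. The authors' log2 fold changes are smaller in size for every named transcript, as 5.40 against 9.35 for uc009urm.1 and -2.33 against -2.43 for uc009mvt.1. A cut at 2 is therefore not the same cut in both. Among the transcripts tested here, 662 of the lower calls in the authors' deposited table lie inside the 3 lower stretches and 1189 outside all stretches.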

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

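Leaving out the 3 lower stretches and thinning all libraries to the lowest total were chosen after seeing the data. The counts of changed, higher and lower transcripts stayed within 1.5 times the reported ones under all settings except a log2 fold change of 1 or more (1266 changed, 961 higher, 305 lower, fewer by construction) and DESeq2 in place of edgeR (1440 lower; 1432 of these also lower by edgeR). Leaving out each library gave 4336 to 4929 changed, 2446 to 2691 higher and 1890 to 2238 lower. The 391 strong increases became 810 with no low-count filter and 433 to 498 with a library left out. The 13 strong decreases became 98 with no filter, 21 with DESeq2 and 8 after thinning. They became 19 to 36 with a library left out: 19, 23 and 20 without wild-type replicate 1, 2 and 3, and 32, 36 and 30 without knockout replicate 1, 2 and 3. The low-count filter was repeated in each of these refits and asks for fewer libraries when a genotype holds fewer. The rises therefore need not mean dependence on single libraries. Except for the threshold, the cause was not tested. Upper-quartile scaling turned the majority of calls to lower (46.5% higher). The shift of the 3 stretches stayed between -0.40 and -0.39 in the 13 settings where it was computed. In each setting the stretches were kept as found with all 6 libraries. A change of scaling also moves transcripts inside and outside them alike. A steady shift was therefore nearly fixed in advance and does not test the stretches. No result changed sign. Apart from uc009cis.1 with DESeq2, no named transcript lost its call, with adjusted p up to 9.18e-10 for uc009urm.1, 3.51e-12 for uc009urj.1 and 7.29e-09 for uc009mvt.1.

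The replicate numbers were not taken to pair the libraries, since the correlation of deviations across transcripts was not above 0.1 in all same-numbered pairs. It was 0.068, 0.090 and 0.023 for pairs 1, 2 and 3 over all tested transcripts, and 0.16, 0.25 and 0.054 at 8 CPM or more. Over all tested transcripts each library correlated best with its own number, a hint from the data only. At 8 CPM or more this held for pairs 1 and 2 (other pairings of these 4 libraries -0.23 and -0.16), while knockout replicate 3 correlated better with wild-type replicate 1 (0.11). With the number as a block 5448 transcripts changed, 2917 higher and 2531 lower, and 391 and 13 passed log2 2. The gene-list and Ehmt2 alternatives were not run, since the identifiers carry no gene names, and those for normalized units do not apply to counts. At this depth 55.2% of 1.5-fold changes were recovered in simulation. That simulation held only 200 planted changes, so its adjusted threshold was harder to pass than with the 5080 calls here. The share therefore does not tell how many changes of that size were missed in the data.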

Other observations

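The tests of the stretches, of expression level and of neighbouring transcripts below were chosen after their results had been seen, and the thinning to the lowest library total was added after the data had been seen. Those of scaling and of other splits of the libraries were set before their own results were seen.

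The transcripts that rose by 2 or more on the log2 scale lay near each other in the table. Of the 391, 125 were within 5 rows of another one, and 49 of them formed 14 groups of 3 or more, the largest with 5 members. There were 92 pairs 1 to 5 rows apart, where labels shuffled within deciles of expression gave a mean of 18.0 (central 95% of 1000 shuffles 10 to 27, permutation p = 0.001, the smallest these shuffles can give). The excess was 5.12 times. At 51 to 200 rows there were 582 pairs against 434 (permutation p = 0.001).

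Transcripts of one gene listed beside each other may account for the closest pairs of strong increases. Pairs 21 to 50 rows apart were still 1.32 times as frequent as in shuffled labels (121 against 91.4, central 95% 73 to 112, permutation p = 0.003). The shuffles moved transcripts singly, so where transcripts of one gene rise together their central 95% is too narrow at every distance. One gene's transcripts may also spread that far. These pairs therefore cannot decide whether transcripts of one gene are the whole cause. Increases shared by neighbouring genes and reads shared between near-identical gene copies both stay open, as neither was tested.

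A minority of regulated transcripts inside the 3 lower stretches would leave the upper quartile of log2 fold changes in place. Inside them, 721 tested transcripts under 8 CPM did not enter the search. Their upper quartile was shifted by -0.46 (95% bootstrap interval -0.55 to -0.36), against -0.42 for the lower quartile. Some of these transcripts may share a gene or reads with transcripts that entered the search. They need not be independent of it, which the interval does not allow for. A candidate explanation is a difference in copy number between the cell lines, which would move all transcripts alike: the interquartile range inside differed from that outside by only -0.024, and no percentile tested in the pooled stretches departed from the median shift by more than 0.070, although in rows 7665 to 8259 and 40746 to 42966 taken alone the highest percentile tested shifted by -0.57 and -0.53. If RNA follows copy number and cells otherwise hold 2 copies, a gain of 1 copy in all wild-type cells would give -0.58. Under these assumptions the ratio of 0.757 would go with an extra copy in 64.1% of wild-type cells or a single copy in 48.5% of knockout cells. Neither assumption was tested, and other copy numbers could give a similar ratio. Even regulation of whole regions by G9a, a difference between individual clones and GC bias stay open, and none was tested. If the stretches are a property of the lines, part of the lower calls may not depend on G9a, and a refit without them called 1786 transcripts lower, of which 1556 were also lower with them included.

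The excess of strong increases, 391 against 13, was set against library scaling, depth and weak expression. The choice among the 3 scalings tried is argued against. The log2 fold changes of the called transcripts would have to move by 0.91 to make the counts equal. The medians under TMM, DESeq2 and upper-quartile factors differed by at most 0.050. An error common to these scalings was not tested, and their spread does not bound it. Depth is argued against because 97.6% of the transcripts past 2 were increases after thinning every library to the lowest total. Transcripts near the detection floor are not the whole cause. Among transcripts with at least 2 CPM in both genotypes 97.4% were increases (76 against 2, exact 95% interval 91.0 to 99.7). The interval takes transcripts as independent. Strong increases lie near each other in the table, so it is too narrow, and it does not cover the spread between libraries. A loss of repression by G9a may explain the excess, but a difference between the lines other than G9a and shared reads stay open, so this is a hypothesis only.

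Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed transcripts, the real one with 5080, and the highest of the others gave 0 (edgeR). Likewise 1 gave as many transcripts past log2 2 in one direction, the real one with 391, with 0 as the highest other. At an unadjusted p under 0.05 the other splits gave 111 to 241 and the real one 6034. DESeq2 was not run on the other splits. Every other split mixes the genotypes in both of its groups, so the genotype difference adds to the spread within them. Low counts in those splits were thus nearly fixed in advance. With 10 splits the share cannot fall under 0.05.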
